A study of Gallus gallus with 8 samples.

How the data were processed

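Liver RNA from 8 chicken embryos on day 11 of incubation was measured on 4 two-colour Agilent arrays of 1 slide. The eggs were specific pathogen free White Leghorn eggs of unknown sex. Per the labels' protocols, 4 eggs received 0.15 ml of deionized water on days 9, 10 and 11, and 4 eggs were left without injection as environmental controls. Each array held 2 eggs of the same group, 1 labelled with the green dye Cy3 and 1 with the red dye Cy5. Each group therefore had 2 Cy3 eggs and 2 Cy5 eggs on 2 arrays. The control arrays were at slide positions 1 and 2 and the water arrays at positions 3 and 4. Group and slide position can therefore not be told apart. In what follows, control array A held control eggs 1 and 2, control array B held control eggs 3 and 4, and the water arrays are named the same way. The labels number the eggs of each group, and nothing in them says that an equal number links a control egg to a water egg.

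Per the labels' protocols, the RNA was amplified and labelled with a low-input kit together with spike-in controls, and per the submitters' processing notes the scans were read with Agilent Feature Extraction. Its version and the background and dye settings are not given in the sources used here. The deposited values are an intensity per array feature on a linear scale, 1 column per egg. Every column had a median of 1, so the authors' scaling divided each column by its own median. In each column all values were whole multiples of 1 unit within a tolerance of 0.01, and the median spot corresponded to between 656 and 949 such units. The table has 45220 numbered features. Of these, 1417 had no value in any egg and were left out, which left 43803. The Cy3 columns held between 43773 and 43803 values and the Cy5 columns between 40445 and 40660. Of the values missing from a Cy5 column alone, between 97.2% and 98.1% lay among the dimmest 25% of features in Cy3. A value in all 8 eggs was present for 37462 features. The number of arrays and eggs limits the precision here.

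The files do not pair the feature numbers with probes or genes. The gene table at hand could not be joined to them, so features are named by number. Gene lists written before the data were examined, and the averaging of probes of 1 gene, were therefore not run, and neither was a fit with embryo sex taken from W chromosome genes. Which spots repeat a probe was not known, so each feature was tested on its own.

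The intensities were taken to log2 as deposited, with no pseudocount and no further scaling. Water and control eggs were compared with limma 3.58.1 in R 4.3.3. The model held dye and group, with the shared array as a random block (duplicateCorrelation, fitted correlation -0.0098), and the moderated test was two-sided. The p-values were adjusted over all 43803 features by the Benjamini-Hochberg method, with a threshold of 0.05. As a second, looser criterion, features with a difference of at least 1.5-fold and an unadjusted p under 0.05 were counted. For the 37462 features with all 8 values the dye term gives the average of the Cy3 and the Cy5 comparison, as the series design describes. Where values were missing, the eggs present set the weights of the dyes, and a feature without a Cy5 comparison rests on Cy3 alone. The features named in the text follow a rule set before the data were examined: those with the smallest p among features at least 1.5-fold apart in the same direction in both dyes, here limited to 2 per direction because no gene names were at hand. The spread between eggs was the standard deviation of the log2 values after removal of each dye's mean within the group, as a median over features. Its ratio between groups was tested exactly over all 36 ways to regroup the eggs within each dye.

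The fit was tested on simulated data with 43803 features, of which 200 were changed, 50 at each of 4 sizes. The noise was independent and normal around the mean of each dye, with the moderated variance of each feature. It held no shared array effects, spot patches or outlying egg. The changed features were drawn from those measured in all 8 eggs. Past an adjusted p of 0.05 it recovered 9 of the 50 features changed 1.5-fold, 29 of those changed 2-fold, 45 of those changed 4-fold and 49 of those changed 8-fold. The looser criterion recovered 31, 48, 50 and 50. Among the unchanged simulated features, 7 passed the adjusted threshold and 550 passed the looser criterion.

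Alternatives set before the data were examined were quantile normalization, centring of columns, removal of the dimmest 25% of features, no array block, eggs of 1 array averaged, a block for the egg number, no dye term, each dye on its own, an intensity trend with robust moderation, a pseudocount of 0.162, an unmoderated test, and each egg left out in turn. Added after seeing the data were a restriction to features measured in all 8 eggs, quantile normalization within each dye, removal of control array B, removal of patches of dim spots with their neighbours, removal of control egg 4 together with quantile normalization within each dye, removal of the local trend in each column with and without its level, and the unmoderated test for the looser criterion. The local trend was the median deviation from the mean of the dye in a window of 11 by 11 spots. The grid of 85 spots per line was inferred from the correlation of values between feature numbers, since no spot positions were used here. Neighbours on this grid were features whose numbers differed by 1, 84, 85 or 86. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.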

Results

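Gene expression was measured in the liver of 8 chicken embryos on day 11 of incubation, 4 from eggs injected with water and 4 from eggs left without injection. The water eggs had received 0.15 ml on days 9, 10 and 11. Per the labels, both sets served as references for other eggs given water-soluble carcinogens. The comparison addresses what the injection of water itself does to liver transcripts, but an effect of slide position cannot be told apart from it. Values were obtained for 43803 array features, of which 37462 were measured in all 8 eggs. Every level is an intensity relative to the median feature of the same egg, on a log2 scale. The features carry numbers and are not paired with genes here.

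No feature differed between water and control eggs past an adjusted p of 0.05 in limma, and the lowest adjusted p was 0.59. An ordinary unmoderated test of the same model also called 0 features. At an unadjusted p under 0.05 there were 3447 features by limma and 4574 by the unmoderated test, where chance alone gives 2190 and the unchanged features of the simulation gave 2435. The limma count was uneven over brightness: 1164 of the 10951 dimmest features, against 725, 870 and 688 in successively brighter groups of about this size. It was 2055 of 32852 with the dimmest 25% of features left out, and 2359 of 37462 among features measured in all 8 eggs. This count moved with the processing: it was 1380 of 37462 features with the eggs of an array averaged and 2179 of 37462 with quantile normalization within each dye, and it ranged from 890 without control egg 3 to 11812 without control egg 2. The looser criterion of at least 1.5-fold with an unadjusted p under 0.05 was met by 587 features, 343 higher and 244 lower in water. These were 1.34% of the features tested. In the simulation of the same size, 550 unchanged features met this criterion. Its noise was independent and normal, without an outlying egg or spot patches, so neither 550 nor 2435 need be the chance count here. Of the 18 splits of the real eggs that balance the dyes, described below, 3 gave at least 587, the real one included. The other balanced splits gave between 146 and 709. The 1.34% is therefore not read as a share changed by water. The labels state a share under 1% for the effect of water without naming the criterion, so the shares are not directly comparable. By the unmoderated test the same criterion was met by 328 features, or 0.749%. The count rested on single eggs and on the treatment of dye: it was 2778 without control egg 2, 1159 without control egg 1, 1174 with no dye term and 977 with the Cy5 eggs only. With both eggs of control array B left out, 3 features passed the adjusted threshold and 953 met the looser criterion. All 3 lay in or beside a patch of dim spots. At each of them control eggs 1 and 2, the control eggs kept, were lower than control eggs 3 and 4, so these calls are not read as an effect of water.

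Most features lay close together in both groups. The difference was within 1.5-fold for 96.0% of features, and 375 differed by at least 2-fold, 144 higher and 231 lower in water. The median standard error of a difference was 0.150 on the log2 scale. In simulated data of this size, 29 of 50 features changed 2-fold and 45 of 50 changed 4-fold passed the adjusted threshold, against 9 of 50 changed 1.5-fold. In such data a small change in single transcripts was thus not detectable in most cases with 4 eggs per group. The simulation held no shared array effects, spot patches or outlying egg, so recovery in the real data may differ.

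Features were named by smallest p among those at least 1.5-fold apart in the same direction in both dyes. By this rule the features higher in water were 43400 and 43742. Feature 43400 had a level of -0.39 ± 0.27 in control eggs and 0.62 ± 0.10 in water eggs (log2, SD, n = 4 each). The difference was 1.01 ± 0.14 (SE), or 2.02-fold, with all 4 water eggs above all 4 control eggs and a limma adjusted p of 0.59. Feature 43742 had a level of 1.53 ± 0.26 in control and 2.25 ± 0.34 in water eggs (SD, n = 4 each). It was 1.64-fold higher in water, a difference of 0.72 ± 0.11 (SE) with the same adjusted p. Both features belonged to 1 cluster of 29 neighbouring spots that met the looser criterion together, and both lay in or beside a patch of dim spots on 1 array. With the local trend of each column removed and the column level kept, an alternative added after seeing the data, the differences were 0.74 for feature 43400 and 0.37 for feature 43742.

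By the same rule the features lower in water were 14614 and 15038. Feature 14614 had a level of 0.10 ± 0.21 in control and -0.83 ± 0.34 in water eggs (SD, n = 4 each), a difference of -0.93 ± 0.12 (SE). Feature 15038 had a level of 0.64 ± 0.19 in control and -0.70 ± 0.41 in water eggs (SD, n = 4 each), a difference of -1.34 ± 0.18 (SE). Control levels were thus 1.91-fold and 2.53-fold those in water, and every control egg lay above every water egg. The choice by smallest p, fold and shared direction favours such a separation, here and for the features higher in water. The adjusted p was 0.59 for each. Neither feature had a neighbouring spot that met the looser criterion in the same direction.

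**Figure D1:**
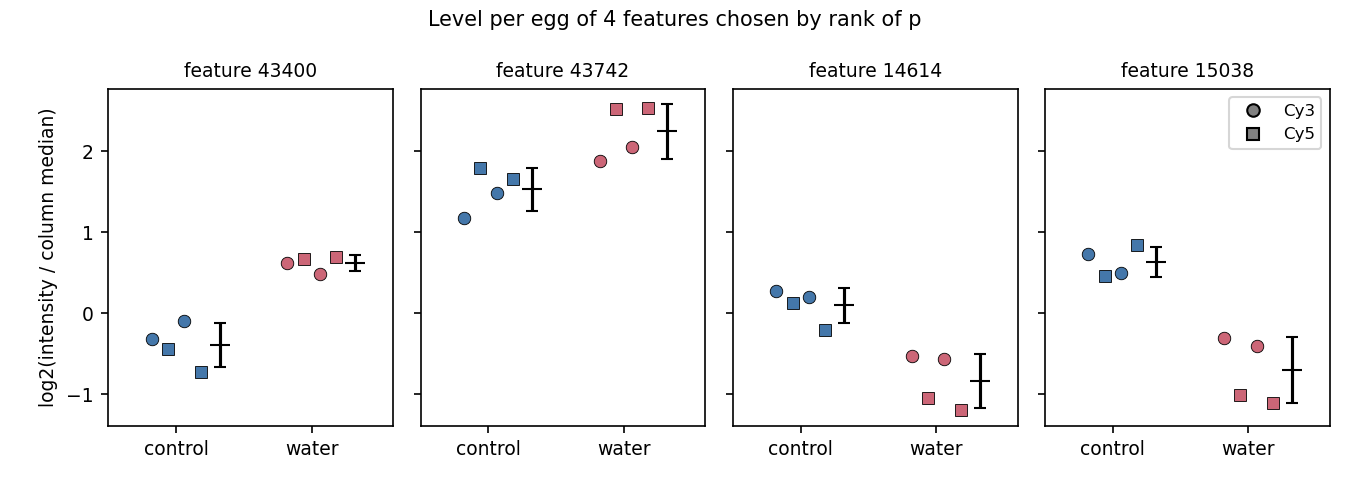
Level of the 4 named features in each egg, as log2 of the intensity over the column median, for control (blue) and water (red) eggs, with circles for Cy3 and squares for Cy5. Bars give the mean ± SD of 4 eggs per group. In each panel the 4 control eggs do not overlap the 4 water eggs, a separation that the choice by smallest p, fold and shared direction favours.

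The Cy3 eggs and the Cy5 eggs give 2 separate comparisons of water with control, each of 2 eggs against 2. Across the 37462 features measured in all eggs, the differences in the 2 dyes as deposited had a Pearson correlation of 0.159 and a Spearman correlation of 0.05; features are not independent replicates, so no p is attached. The sign was shared by 50.4% of features. Both dyes read the same spots of the same 4 arrays, so contrasts that do not part the groups were computed in the same way. Arrays A against arrays B gave a Pearson correlation of 0.219, a Spearman correlation of 0.247 and a shared sign at 58.7%, and the remaining way to pair the arrays gave -0.025, -0.019 and 50.1%. After quantile normalization within each dye, added after seeing the data, the Pearson correlation was 0.345 for water against control, 0.218 for arrays A against arrays B and -0.03 for the remaining pairing. The Spearman correlations were then 0.354, 0.23 and -0.018, and the sign was shared by 62.7%, 58.2% and 49.3%. Among the brighter 50% of features as deposited, the Pearson correlations were 0.306, 0.223 and -0.031, and the sign was shared by 42.7%, 56.5% and 47.6%. No test of the difference between these contrasts was made. Of these contrasts, only water against control also set slide positions 1 and 2 against positions 3 and 4. As deposited, of the 623 features at least 1.5-fold apart between water and control in both dyes, 74.2% had the same direction. For arrays A against arrays B it was 71.7% of 434 features, and for the remaining pairing 52.2% of 580. With patches of dim spots left out these shares were 69.4% of 516, 62.7% of 322 and 43.3% of 476. After quantile normalization within each dye they were 83.4% of 555 for water against control, 73.1% of 431 for arrays A against arrays B and 52.9% of 565 for the remaining pairing. The direction of the general shift depended on brightness and dye. In the dimmest 25% of features the median difference was 0.24 in Cy3 and 0.01 in Cy5, and in the brightest 25% it was -0.13 in Cy3 and 0.31 in Cy5.

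**Figure D2:**
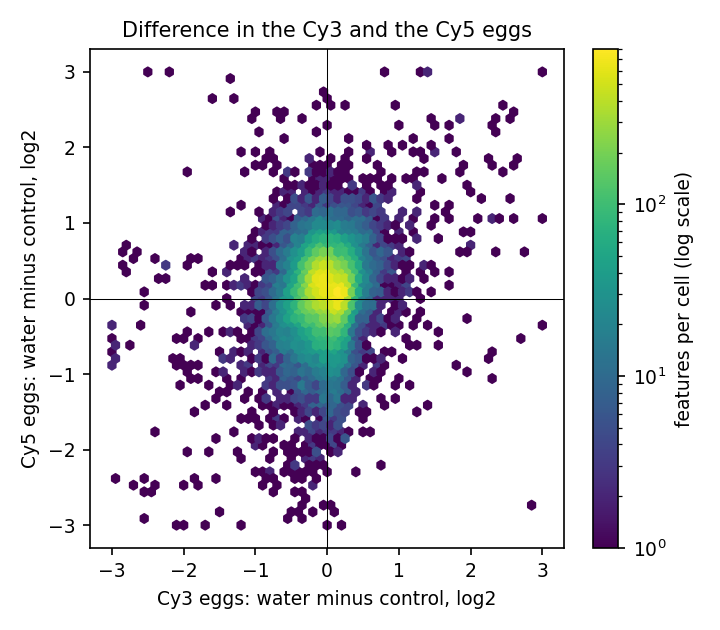
Difference between water and control (log2) in the Cy5 eggs against that in the Cy3 eggs for 37462 features, with values beyond 3 in either direction drawn at the edge and colour giving the number of features per cell on a log scale. Values are as deposited, with a Pearson correlation of 0.159, which was 0.345 after quantile normalization within each dye.

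The split between higher and lower features depended on the dye and on the level and scaling of the columns. As deposited, 58.4% of the 587 features were higher in water. With the Cy3 eggs only, 195 of 678 features were higher and 483 lower, and with the Cy5 eggs only, 746 of 977 were higher and 231 lower. After quantile normalization 540 features met the looser criterion, of which 48.5% were higher. With the local trend of each column removed together with its level, 153 were higher and 435 lower, and the median difference over all features moved from 0.09 to -0.01. With the local trend removed and the column level kept, 297 were higher and 240 lower.

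The median SD between eggs was 0.24 in control and 0.14 in water on the log2 scale, a ratio of 0.583. An exact two-sided test over the 36 regroupings of eggs within dye gave p = 0.111, and the smallest p this design allows is 0.0556. Even the most extreme ratio would give only this smallest p, so the test cannot decide whether the spread differs between the groups. The regrouped ratios ran from 0.563 to 1.775. Control egg 4, described next, is part of every regrouping, so these ratios carry its distance from the other eggs as well. By dye, the median SD was 0.29 for the Cy5 control pair, which includes control egg 4, and 0.09 for the Cy3 control pair, against 0.14 and 0.08 in water. In control egg 4, 3252 features, or 8.68%, lay at least 2-fold away from every other Cy5 egg, 1721 higher and 1531 lower, against between 101 and 243 features in the other 7 eggs. Its levels correlated with those of the other Cy5 eggs at between 0.95 and 0.96, and all other same-dye pairs at between 0.981 and 0.991 (Pearson, log2, across features). Without control egg 4, 824 features met the looser criterion, 298 higher and 526 lower in water, and 373 of these were among the original 587.

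**Figure D3:**
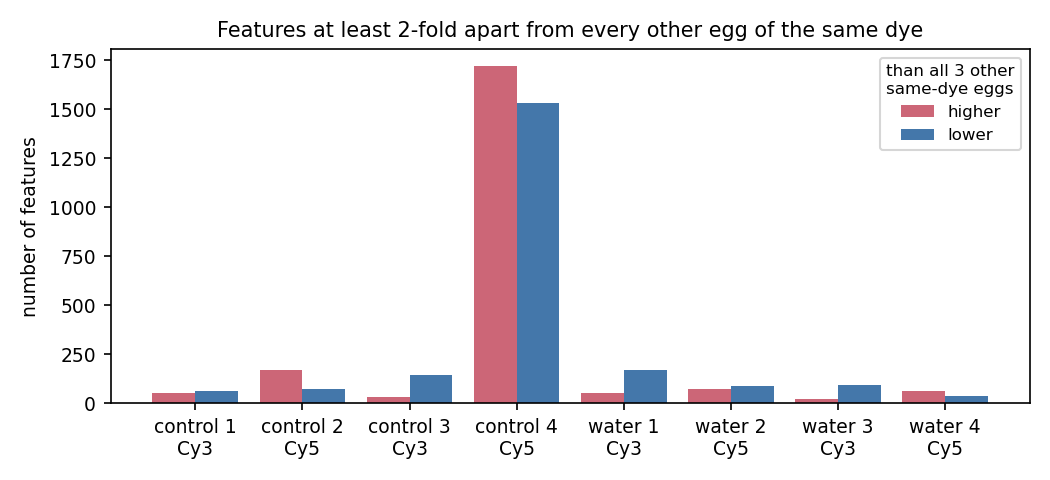
Number of features in each egg at least 2-fold higher (red) or lower (blue) than all 3 other eggs labelled with the same dye. Control egg 4 has 1721 higher and 1531 lower features, more than any other egg.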

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

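All tests of an explanation in this part were chosen after the results were seen. Of the 10 groups of 4 eggs examined for a single distant egg, 2 held one, and chance gives about 1 in 20.

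Control egg 4 stood far from the other control eggs in the number of features at least 2-fold apart from every other egg of its dye, with 3252 features against 117, 243 and 176 in control eggs 1 to 3. A local defect on the array would place these features side by side, yet 46.2% had such a neighbour where random sets of the same size had 45.3%, a ratio of 1.02. A different intensity range of this channel would be removed by quantile normalization within Cy5, after which 3080 features were still apart, against at most 258 in the other Cy5 eggs. RNA of another tissue in the dissected sample may contribute, since 490 features were at least 4-fold higher than in all other Cy5 eggs; but 113 were at least 4-fold lower outside dim patches, against at most 8 in the other Cy5 eggs, which added RNA would not give on its own, so this stays open, and without gene names no marker could be examined. The groups of the design give no biological explanation for an egg apart from its own group, and none was tested; embryo sex, unknown for these eggs, and RNA quality were not tested either.

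Feature 43742 held the other flagged value, with water egg 1 at 1.875 on the log2 scale, the lowest of the 4 water eggs once the dye means were removed. The flag sets the gap to the nearest egg against the range of the group (ratio 0.968). The distance itself was small, since the other Cy3 water egg, water egg 3, was at 2.048. Feature 43742 belongs to the cluster of neighbouring spots described next.

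The 587 features at least 1.5-fold apart with an unadjusted p under 0.05 were set against splits of the 8 eggs into 4 and 4. Of the 34 splits that a dye term allows, the real one included, 10 gave as many or more, the highest with 3668. Among the 18 splits that balance the dyes, 3 did. Chance can therefore not be excluded. The other splits that keep the eggs of an array together gave 494 and 447, under the real count, but are too few for a test. The 4 splits with several times the real count (2414 to 3668) were all unbalanced for dye and had control egg 4 as the only Cy5 egg on its side, a structure that points to this egg, while the highest other balanced split gave 709. With a real count of 0 at the adjusted threshold (highest other 16), all 34 splits give as many by construction, which says nothing about chance. Local spot effects are a candidate explanation for part of the higher features: 22.2% of the 343 had another beside them, against 6.0% in random sets with an upper limit of 9.9%, and 29 formed a single cluster that holds features 43400 and 43742. With the local trend removed and the column level kept, 72.6% of the higher and 82.4% of the 244 lower features still met the criterion. With the level kept, their median difference went from 0.73 to 0.69 in the higher and from -0.74 to -0.71 in the lower features. As the whole cause, a trend as wide as the window is thus argued against for most features of each direction, and stays open for the rest. With the column level removed as well, 43.7% of the higher and 98.8% of the lower ones met the criterion. That version also moved the median difference over all features from 0.09 to -0.01, which favours the lower direction. These 2 shares therefore decide nothing about a trend. The trend was a median over a window of spots, so patches much smaller than the window would remain and are not tested. Among the lower features 8.2% had a neighbour, at the limit of 8.2% from random sets. A local part there stays open, as does an effect of water for either direction.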

How the results depend on the processing

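The local trend, within-dye quantile, patch, all-egg and array alternatives and the unmoderated count at 1.5-fold were chosen after seeing the data. No feature passed an adjusted p of 0.05 by limma in the original fit, where 3447 had an unadjusted p under 0.05. A single feature passed with Cy3 eggs only. With control array B left out 3 passed, all in or beside patches of dim spots. These 3 were lower in control eggs 1 and 2, on the control array kept, than in control eggs 3 and 4. Leaving out 1 egg at a time gave between 0 and 2. The count at 1.5-fold and an unadjusted p of 0.05, originally 587, was 1174 with no dye term, 977 with Cy5 eggs only (746 higher, 231 lower; Cy3 eggs only 195 higher, 483 lower), 953 with control array B left out and 328 by the unmoderated test. It ranged from 444 to 2778 when 1 egg was left out, and was 2778 without control egg 2 and 1159 without control egg 1. Without control egg 2, control egg 4 was the only Cy5 control egg. The ratio of the spread in water to that in control, originally 0.583, ranged from 0.333 (without water egg 2 or 4) to 1.47 (without control egg 2 or 4); both ends set the Cy3 pair of 1 group against both dyes of the other, so they say nothing about single eggs. The cause of the other changes was not tested. The egg number as a replicate block gave 614 features and 0 past the adjusted threshold; deviations of same-numbered eggs correlated at 0.325 to 0.708 and those of other eggs of the same dye at 0.399 to 0.697, and 3 of 8 eggs correlated best with their own number, so no link beyond the dye was seen. In the other alternatives the count stayed within 1.5 times. The 4 named features, whose direction the choice by both dyes largely fixes, had sizes from 0.27 (feature 43742 with the local trend and column level removed) to 1.71 and passed the threshold in none of 102 alternative values. Gene lists, averaging of probes of a gene and the W chromosome covariate were not run for lack of gene names.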

Other observations

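The tests in this part were chosen after the results were seen. Features dim in both dyes of a single array came in patches. At least 2-fold below every other egg of the dye, in both dyes of the array, lay 65 features on control array B, 28 on water array A, 12 on water array B and 6 on control array A. Of these 111 features, 64.0% had another such feature beside them, where random sets gave 1.9% with an upper limit of 5.41%. On water array B none of the 12 did. Local spot failure is a likely source of the clustered part on the other 3 arrays. An egg-specific level would have to appear in both eggs of 1 array at once. The labels name nothing that set the 2 eggs of an array apart together beyond their group and the array. Embryo sex was unknown and could have been shared as well.

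Of the 12 features on water array B, 7 lay at least 1.5 on the log2 scale below every other egg of the dye in both dyes. The median level of these 7 was 0.35 there against 8.11 on the other arrays in Cy3, and 2.03 against 4.17 in Cy5. All 7 had a Cy3 level at least 4-fold above the Cy5 level on the other arrays, as 0.11% of all features did.

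Features with a wide gap between eggs did not part the 2 groups. A gap of at least 1.5 on the log2 scale in both dyes set whole arrays apart at 64 features and followed other patterns at 64 more. None of these features separated the water from the control eggs. Where whole arrays were apart it was always a single array. The other ways to pair the arrays gave no such feature either, so this absence is not particular to the treatment.

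Both water eggs exceeded both control eggs in each dye at 2360 features, or 6.3%, and both lay below at 815 features, or 2.18%, where chance would give 2.78% for each direction if the dyes were independent. They were not, since both dyes read the same 4 arrays, and the median difference over all features was 0.09 as deposited and 0.02 after quantile normalization, so no excess is read from these shares. With a difference of at least 1.5-fold as well, the counts were 243 and 199.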
